A study of Homo sapiens with 16 samples.

How the data were processed

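Messenger RNA levels were measured on 16 two-colour Agilent expression arrays. Each array carried RNA from 1 of 8 established non-small cell lung cancer lines after 24 hours in 50 nM or 100 nM of a compound the labels call AUY, together with RNA from matched untreated cells of the same line. The labels do not spell the compound out; from general knowledge of this kind of study it is taken to be the HSP90 inhibitor NVP-AUY922. Per the labels' protocols, A549 was grown in Ham's F12, H1155 and H1435 in ACL-4, H1793 in HITES and the remaining lines in RPMI, so the medium differs between lines but not within an array. Total RNA was labelled with Cy3 or Cy5 by the Quick-Amp method, per the labels' protocols.

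Per the file headers, the images were quantified with Agilent Feature Extraction 9.5.1.1 on array design 014850, annotated on human genome build hg17. Its intensity values per the file headers are the mean pixel brightness of each spot and the median pixel brightness of its local background in each channel. Background correction was switched off in that protocol, per the file headers. The same files give a dye-normalized log10 ratio of red over green, and the authors' deposited series table holds log10 ratios of the same kind. Regression of each deposited column on its scanner file gave slopes between 0.99991 and 1, so the deposited table is that ratio averaged over the spots of a probe.

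The labels assign Cy5 to both channels of every array. The treated channel carries the Cy5 label on all 16 arrays, so Cy5 over Cy3 is likely treated over untreated, in the same orientation on every array. No array was turned round by its values. There were no dye swaps, so a gene-specific dye effect cannot be separated from treatment in the comparisons of a dose with untreated cells. Such an effect cancels in the difference between doses and between cell lines.

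Net intensities were computed in R 4.3.3 with limma 3.58.1 (files read with version 1.17.8 of data.table). Local background was subtracted by the normexp method with an offset of 50, and ratios were normalized within each array by loess. A local background above 2 times its array's median was replaced by that median, which touched 0 to 45 spots per array. This replacement was chosen after first results had been seen, because single spots with backgrounds up to 60154 disturbed the normexp fit on some arrays. Control spots and spots marked as outliers by the scanner software were left out, and spots of a probe were averaged. All ratios are given as log2.

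Detection was planned from the scanner's flag for signal above background. That flag was set on every spot, dark corners included, so a channel was instead called detected when its net signal exceeded the mean plus 3 SD of the array's 153 negative control spots. This change was made after the files had been seen. Probes detected in either channel on at least 4 arrays were kept, which left 34336 of 41000 probes. Gene names came from the annotation in the scanner files, brought to current symbols through a table of assembly GRCh38.p14 that was used for names only. The brightest probe stood for a gene, which gave 25677 genes or sequences, 15705 of them with a current symbol.

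Precision is limited by the number of arrays. Median net intensity per array ran from 80.7 to 139.7 in Cy3 and from 180 to 339 in Cy5. Between 69.2% and 78.4% of probe spots were detected in Cy3, and between 64.7% and 81.0% in Cy5. Per the file headers, spike-in transcripts of known ratio gave slopes of 0.713 to 0.724 in H1793 and H2172 and of 0.772 to 0.830 in the other lines. The scanner's ratios were therefore compressed, and most so in those 2 lines. No slope was computed for the ratios normalized here.

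Each dose was compared with untreated cells by limma (lmFit and eBayes) on the mean log2 ratio of the 8 lines against 0. The doses were compared by the same test on the 8 within-line differences, which pairs the arrays by cell line. Differences between lines were tested by limma's F-test over the line coefficients of a model with line and dose on all 16 arrays. P-values were adjusted by the Benjamini-Hochberg method over the genes, with a threshold of 0.05. The labels give no repeat culture of a line, and the untreated RNA of a line may be shared by its 2 arrays. P-values between lines therefore measure only the spread between the 2 arrays of a line, which may be technical.

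The 26 gene lists were written before the data were examined, as were the tests and the rule for named genes. They cover the heat shock response, HSP90 and its co-chaperones, HSP90 client kinases and receptors, the chaperonin TRiC and prefoldin, ER chaperones and the unfolded protein response, ATF4 and the integrated stress response, and cytosolic aminoacyl-tRNA synthetases. Others cover MAPK pathway output, DNA replication and G1/S, mitosis and G2/M, p53 targets, NF-kB and inflammatory genes, the interferon response, apoptosis and the BCL2 family, proteasome subunits, autophagy and lysosome, and cytosolic ribosomal proteins. The rest are NRF2 targets, hypoxia and glycolysis, cholesterol synthesis, cytoskeleton and SRF targets, and markers of epithelial, mesenchymal, neuroendocrine, leukocyte and lung lineage cells. Between 13 and 56 members of each were measured. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The median of each list in each line was tested by an exact two-sided sign-flip test over the 8 lines, whose smallest possible p is 0.0078. Differences of a list between lines were tested by an exact permutation test over 40320 assignments of the 50 nM arrays to lines.

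Named genes follow this rule. At 100 nM they are the 12 highest and 12 lowest means among genes past the threshold with 1 sign in all 8 lines. For each list they are up to 4 called members with the largest mean, or 2 members where none was called. HSPA1A, HSPA8, DNAJB1, HSP90AA1, HSP90AB1, HSF1 and EGFR were always included. For the dose difference the rule takes up to 5 called genes in each direction, and between lines the 10 called genes with the largest range of line means. For each line it takes the 3 genes farthest above and the 3 farthest below the median of the other 7 lines, which are described without a test. Only probes with a proper gene symbol counted, and XIST and Y-linked genes were left out. Of the 111 genes named by mean at 100 nM, by list or always, 48 had several kept probes. In 22 of these another probe had a mean of opposite sign at 100 nM, or one smaller by a factor of more than 2. Not every such probe is given below. Some genes that this rule names are not reported here.

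The tests, apart from the permutation test of lists between lines, were first run on simulated data with the real spread. These held 200 changed genes among 25329, or 198 for the test between lines. At 100 nM 64.7% of genes changed by 0.5 on the log2 scale were recovered, 90.9% of those changed by 1 and all of those changed by 2, with 11 unchanged genes called. At 50 nM the shares were 50.0%, 77.3% and 98.5%, with 5 unchanged genes called. For the dose difference 97.1% were recovered at a change of 0.5, with 6 unchanged genes called. Between lines 69.2% were recovered at a size of 0.5 and 97.0% at a size of 1, with 11 unchanged genes called. In each of the 3 list comparisons 1 unshifted list passed camera. Genes were simulated as independent of each other. In the real data the estimated correlation within lists at 100 nM ran from -0.028 for neuroendocrine markers to 0.80 for mitosis genes. The simulation therefore cannot show how often camera at its preset calls unshifted lists of correlated genes.

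The alternatives tried were no background subtraction, the scanner's own ratios, the deposited table, median centring in place of loess, scaling between arrays, no detection filter, a strict detection filter, the mean of a gene's probes, and eBayes with a trend. Random blocks for cell line or slide, an unpaired test of the doses, only the lines with both arrays on 1 slide, and each line left out in turn were also planned. Further alternatives were chosen after seeing the data. These were the local backgrounds as given, a normexp offset of 1, division by the spike-in slope, omission of H1793 and H2172, a random block for scan day, and only the lines scanned on 1 day. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.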

Results

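Gene expression was measured in 8 established non-small cell lung cancer lines, A549, H1155, H1435, H1793, H1975, H2172, H23 and HCC827. Each line was treated for 24 hours with 50 nM or 100 nM AUY, taken here to be the HSP90 inhibitor NVP-AUY922. HSP90 is a chaperone that stabilizes many kinases and receptors. Each of the 16 arrays compared treated with matched untreated RNA of 1 line, so there were 8 arrays per dose and 1 array per line and dose. After removal of dim probes, 25677 genes or sequences were tested. Ratios are log2 of Cy5 over Cy3, and the labels give Cy5 to both channels. Because the treated channel carries Cy5 on every array, a positive value likely means a higher level in treated cells. Heat shock genes had a median above 0 on all 16 arrays, between 0.42 and 1.05. No dyes were swapped, so values against untreated cells may include gene-specific dye effects.

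The first comparison asked which transcripts changed after 24 hours at 100 nM AUY. Chaperone genes of the heat shock response rose, led by HSPA1A, the inducible cytosolic HSP70, at 3.42 ± 1.32 (SD, n = 8 lines) on its brightest probe, a mean of 10.7-fold. That probe was saturated on 2 of the 8 arrays and its untreated signal in H1155 was not above the negative controls, and the other 2 probes gave 6.35-fold and 6.41-fold. HSP90AA1, the inducible HSP90 itself, rose by 2.04 ± 0.61, and the constitutive HSP70 gene HSPA8 rose by 1.84 ± 0.55. The growth factor response gene EGR1 fell by 3.77 ± 0.78, a mean of 13.7-fold. DUSP6, the ERK phosphatase induced by MAPK signalling, fell by 3.50 ± 1.66, and the DNA replication factor CDC45 fell by 2.34 ± 0.97. In all, 7265 genes passed an adjusted p of 0.05 (limma), 3538 higher and 3727 lower, and 149 rose and 272 fell by 2-fold or more. Of the called genes, 2229 were higher and 2347 were lower in all 8 lines. All 8 lines had 1 sign for 19.3% of the genes, where 0.781% would be so by chance. With median centring in place of loess, 12478 genes passed, and 70.5% of them were higher.

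**Figure D1:**
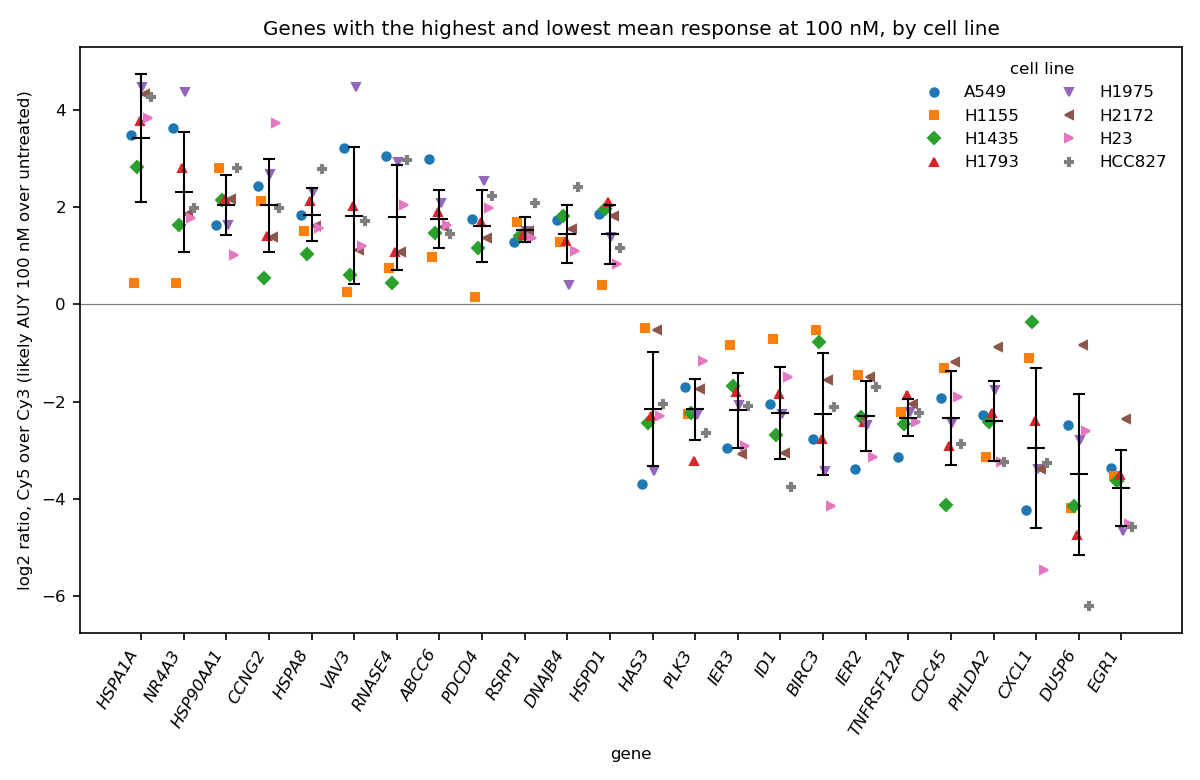
Log2 ratio (Cy5 over Cy3, likely AUY 100 nM over untreated) of the 12 genes with the highest and the 12 with the lowest mean. Only called genes with 1 sign in all 8 lines were ranked. Each symbol is 1 cell line, and bars are the mean ± SD of 8 lines. HSPA1A is at 3.42 ± 1.32 with H1155 at 0.44, and EGR1 is at -3.77 ± 0.78.

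The 12 genes with the highest means at 100 nM were taken among called genes with 1 sign in all 8 lines. Called genes of mixed sign, such as CTH below, were left out even where their mean was higher. The 12 held the chaperone genes HSPA1A, HSP90AA1, HSPA8, DNAJB4 at 1.45 ± 0.59 and the mitochondrial chaperonin HSPD1 at 1.44 ± 0.61. The others included the nuclear receptor NR4A3 at 2.31 ± 1.24, the cyclin CCNG2 at 2.03 ± 0.96, and the translation inhibitor PDCD4 at 1.60 ± 0.74. The guanine nucleotide exchange factor VAV3 had a mean of 1.82 ± 1.40, RNASE4 of 1.79 ± 1.09, the transporter ABCC6 of 1.75 ± 0.59 and RSRP1 of 1.53 ± 0.26. By that rule all were called and higher in 8 of 8 lines, with adjusted p between 5.6e-05 and 0.011. Untreated NR4A3 and VAV3 were above the negative controls in 7 of 8 lines, so their means are not exact. The lowest mean among a gene's other probes was 0.36 for NR4A3, 0.39 for CCNG2, 0.51 for VAV3, 0.04 for ABCC6, 0.69 for HSPD1 and 0.01 for RSRP1, for which another probe gave 1.82. The brightest HSPA1A probe was saturated on 6 arrays, and its other probes gave means of 2.67 and 2.68. That probe lies on chromosome 6 at 31893470 to 31893529 (hg17).

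The 12 genes with the lowest means were chosen by the same rule, and so were lower in 8 of 8 lines. Their adjusted p lay between 5.6e-05 and 0.0023. Besides EGR1 (probe on chromosome 5 at 137832790 to 137832849, hg17), DUSP6 and CDC45, they held the chemokine CXCL1 at -2.95 ± 1.64 and the apoptosis inhibitor BIRC3 at -2.26 ± 1.26. The immediate early genes IER2 and IER3 had means of -2.30 ± 0.72 and -2.18 ± 0.77. TNFRSF12A, the receptor for TWEAK, was at -2.33 ± 0.38 and PHLDA2 at -2.40 ± 0.82. ID1, an inhibitor of DNA binding, was at -2.24 ± 0.95, the kinase PLK3 at -2.16 ± 0.63 and the hyaluronan synthase HAS3 at -2.15 ± 1.17. A second HAS3 probe gave -0.05. Treated CXCL1 was above the negative controls in 7 of 8 lines at 100 nM, as was treated DUSP6. Among the list members named below, the lower channel was above them in 7 of 8 lines for NUPR1, MET, AKR1C1, AKR1C3, ABCC3, EPCAM, SNAI2, COL1A1 and ENO2 and in 6 for EREG, KRT7, CORO1A and NKX2-1, so these means are not exact either.

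Of 34 measured heat shock genes, 26 rose and 0 fell at 100 nM, and 28 rose when adjusted over the list alone. The line medians averaged 0.73 ± 0.21 and lay above 0 in 8 of 8 lines (exact sign-flip p = 0.0078, adjusted p = 0.025; camera adjusted p = 3.3e-14, but adjusted p = 0.10 with an estimated correlation). DNAJB1, an HSP40 co-chaperone, rose by 1.07 ± 0.25. Of 23 HSP90 and co-chaperone genes, 11 rose and 4 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.024; adjusted p = 0.19 with an estimated correlation). HSP90AB1, the constitutive HSP90, rose by 0.96 ± 0.22 and AHSA2P by 0.75 ± 0.39, while the immunophilin FKBP5 fell by 1.06 ± 0.62. HSF1, the transcription factor of the heat shock response, was at -0.24 ± 0.15 (adjusted p = 0.020), but at 0.48 with median centring.

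Of 45 DNA replication and G1/S genes 44 fell and 0 rose, also when adjusted over the list alone. Their line medians averaged -1.08 ± 0.58 and lay below 0 in 8 of 8 lines (exact sign-flip p = 0.0078; camera adjusted p = 1.9e-21, but adjusted p = 0.37 with an estimated correlation). The clamp loader subunit RFC4 fell by 1.86 ± 1.12, the ribonucleotide reductase subunit RRM2 by 1.75 ± 0.85 and the helicase subunit MCM7 by 1.74 ± 0.45. Mitosis and G2/M genes went the other way, with 15 of 40 higher and 1 lower, or 17 and 1 when adjusted over the list alone. Their line medians averaged 0.37 ± 0.54 and lay above 0 in 7 of 8 lines (exact sign-flip p = 0.086; camera adjusted p = 0.00016, but adjusted p = 0.71 with an estimated correlation). The kinetochore protein CENPF rose by 1.41 ± 0.54, the kinase NEK2 by 1.16 ± 0.63, ASPM by 1.09 ± 0.54 and CKS2 by 0.99 ± 0.51.

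Output genes of the MAPK pathway were lower, with 19 of 24 called and 0 higher, or 21 lower when adjusted over the list alone. Their line medians averaged -1.15 ± 0.39, below 0 in 8 of 8 lines (camera adjusted p = 5.8e-12, but adjusted p = 0.10 with an estimated correlation). The EGFR ligand EREG had a mean of -1.98 ± 1.55. Of 27 NF-kB and inflammatory genes 12 fell and 0 rose, and 17 fell when adjusted over the list alone (line medians -0.60 ± 0.42; camera adjusted p = 1.6e-06, but adjusted p = 0.37 with an estimated correlation). RELB, a subunit of NF-kB, fell by 1.59 ± 0.77. The chemokine CXCL8 had a mean of -1.50 ± 1.06, and its treated channel was above the negative controls in 5 of 8 lines.

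Of 56 cytosolic ribosomal protein genes, 44 rose and 0 fell, or 47 and 0 when adjusted over the list alone, by small amounts. Their line medians averaged 0.29 ± 0.11, above 0 in 8 of 8 lines (camera adjusted p = 9.3e-14, but adjusted p = 0.19 with an estimated correlation). RPS2 rose by 0.67 ± 0.24, RPL23 by 0.65 ± 0.26, RPL26 by 0.58 ± 0.20 and RPL12 by 0.57 ± 0.27. Probe means ran from -0.25 to 0.73 for RPS2, from -0.03 to 0.65 for RPL23 and from 0.27 to 0.57 for RPL12.

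Camera called 4 further lists lower, by small amounts, and the mean of each list turned positive with median centring. The proteasome list then passed camera as higher (mean 0.53, adjusted p = 0.00018; 0.54 and adjusted p = 0.00025 at 50 nM), and the other 3 did not pass. Over all lists at 100 nM, camera called 4 higher and 7 lower with loess, but 11 higher and 3 lower with median centring. By fry 3 of the 11 lists called with loess did not pass, mitosis (adjusted p = 0.14), ATF4 (adjusted p = 0.10) and proteasome (adjusted p = 0.065). Of 29 ER chaperone and unfolded protein response genes 14 fell and 1 rose, or 16 and 1 when adjusted over the list alone (line medians -0.24 ± 0.13; camera adjusted p = 0.00050, but adjusted p = 0.42 with an estimated correlation). MANF, an ER stress protein, fell by 1.33 ± 0.31 and SDF2L1 by 1.23 ± 0.28. SEL1L, of ER-associated degradation, rose by 0.72 ± 0.22, with a second probe at 0.00, and the stress sensor ERN1 was at -0.68 ± 0.69, with another at 0.08. Of 20 cytosolic aminoacyl-tRNA synthetase genes 12 fell and 0 rose, or 13 and 0 when adjusted over the list alone (line medians -0.33 ± 0.22; camera adjusted p = 0.00013, but adjusted p = 0.58 with an estimated correlation). FARSB fell by 0.78 ± 0.34, with another probe at -0.14, and FARSA by 0.64 ± 0.21. MARS1 was at -0.69 ± 0.45 and TARS1 at -0.60 ± 0.44, and both turned positive with median centring. Of 31 proteasome subunits 12 fell and 1 rose, or 13 and 1 when adjusted over the list alone (line medians -0.19 ± 0.16; camera adjusted p = 0.00050, but adjusted p = 0.71 with an estimated correlation). PSMD11 fell by 0.65 ± 0.40, PSMD13 by 0.62 ± 0.37 and PSMC3 by 0.60 ± 0.35, while PSMC5 was at -0.48 ± 0.36 and turned positive with median centring. Of 29 ATF4 and integrated stress response genes 6 fell and 2 rose, or 8 and 3 when adjusted over the list alone (line medians -0.19 ± 0.33; camera adjusted p = 0.024, but adjusted p = 0.71 with an estimated correlation). The pseudokinase TRIB3 fell by 1.44 ± 0.62 and CEBPG by 1.11 ± 0.29. CTH, an enzyme of cysteine synthesis, rose by 2.50 ± 2.06, higher in 6 of 8 lines, and NUPR1 by 0.89 ± 0.87. This list's camera call was lost without H1155 (adjusted p = 0.16) and without H2172 (adjusted p = 0.080).

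HSP90 client kinases and receptors did not move as a group, with 6 of 34 higher and 7 lower, or 7 and 8 when adjusted over the list alone (camera adjusted p = 0.73). The telomerase gene TERT fell by 1.20 ± 0.81, the checkpoint kinase CHEK1 by 0.79 ± 0.49, the receptor MET by 0.75 ± 0.55 and CDK4 by 0.74 ± 0.24. EGFR was at -0.0036 ± 0.27 (adjusted p = 0.98, higher in 4 of 8 lines), and at 0.37 with median centring. Of 28 p53 targets 3 rose and 6 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.29). CCNG1 rose by 1.21 ± 0.52 and TP53INP1 by 1.12 ± 0.98, while the nuclease AEN fell by 1.00 ± 0.66. Among 28 apoptosis and BCL2 family genes 5 rose and 11 fell, or 6 and 13 when adjusted over the list alone (camera adjusted p = 0.13). The caspase CASP9 rose by 1.37 ± 1.22, and the survival genes BCL2A1 and MCL1 fell by 0.86 ± 0.27 and 0.85 ± 0.41.

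The remaining 12 lists did not pass camera at 100 nM, with adjusted p from 0.12 to 0.96. With median centring 6 of them passed as higher, NRF2 (adjusted p = 0.0015), autophagy (0.0013), TRiC (0.00033), cholesterol (0.0045), hypoxia (0.015) and cytoskeleton (0.044), the last 4 with means below 0 under loess. The cytoskeleton list passed as lower with the mean of a gene's probes (adjusted p = 0.031), without H1975 (0.025) and without HCC827 (0.046). Of 26 NRF2 targets 7 rose and 3 fell, or 7 and 4 when adjusted over the list alone. The aldo-keto reductases AKR1C1 and AKR1C3 were at 1.25 ± 1.23 and 1.05 ± 0.88, the ferritin gene FTL at 0.63 ± 0.37 and the transporter ABCC3 at -0.82 ± 0.67. Of 33 interferon response genes 6 rose and 5 fell, or 7 and 5 when adjusted over the list alone, with IFIT1 at 1.40 ± 0.84, IFIT2 at 0.73 ± 0.72, TAP1 at -0.86 ± 0.53 and OAS3 at -0.65 ± 0.38. Of 32 hypoxia and glycolysis genes 4 rose and 9 fell, or 5 and 10 when adjusted over the list alone. In that list HK2 was at -0.91 ± 0.81, SLC2A1 at -0.71 ± 0.69, P4HA2 at 0.86 ± 0.66 and MXI1 at 0.68 ± 0.40. Of 26 cholesterol synthesis genes 4 rose and 3 fell, with the same counts when adjusted over the list alone. Among them HMGCS1 at 0.56 ± 0.60, EBP at -0.82 ± 0.36 and PMVK at -0.67 ± 0.29. Of 31 autophagy and lysosome genes 2 rose and 5 fell, with the same counts when adjusted over the list alone. UVRAG was at -0.49 ± 0.15, TFEB at -0.46 ± 0.46, ATG7 at -0.52 ± 0.18 with a second probe at -0.01, and ATG3 at -0.44 ± 0.27, which turned positive with median centring.

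Of 16 TRiC and prefoldin genes 2 rose and 2 fell, or 3 and 4 when adjusted over the list alone. CCT4 was at 0.44 ± 0.22 and PFDN4 at 0.20 ± 0.14, while PFDN2 at -0.66 ± 0.28 and CCT2 at -0.35 ± 0.34 turned positive with median centring. Of 27 cytoskeleton and SRF targets 6 fell and 0 rose, with the same counts when adjusted over the list alone. KLF6 was at -0.99 ± 0.68, while TUBB3 at -0.64 ± 0.40, TPM4 at -0.59 ± 0.32 and TAGLN2 at -0.54 ± 0.31 turned positive with median centring. In the 20 epithelial markers 3 rose and 2 fell, with the same counts when adjusted over the list alone, among them JUP at 0.82 ± 0.57, EPCAM at 0.63 ± 0.67, DSP at 0.55 ± 0.27 and KRT7 at -0.61 ± 0.53. In the 20 mesenchymal markers 1 rose and 1 fell, COL1A1 at 0.53 ± 0.54 and SNAI2 at -0.63 ± 0.52, and 0 when adjusted over the list alone. In the 17 neuroendocrine markers 2 rose and 1 fell, SYT1 at 1.00 ± 0.58, UCHL1 at 0.52 ± 0.49 and ENO2 at -0.48 ± 0.48, or 1 and 0 when adjusted over the list alone. In the 13 leukocyte markers 1 rose and 1 fell, CD79A at 0.44 ± 0.36 and CORO1A at -0.54 ± 0.49, with the same counts when adjusted over the list alone. In the 15 lung lineage markers 2 rose and 0 fell, NKX2-1 at 0.66 ± 0.71 and AGER at 0.48 ± 0.16, or 1 and 0 when adjusted over the list alone.

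**Figure D2:**
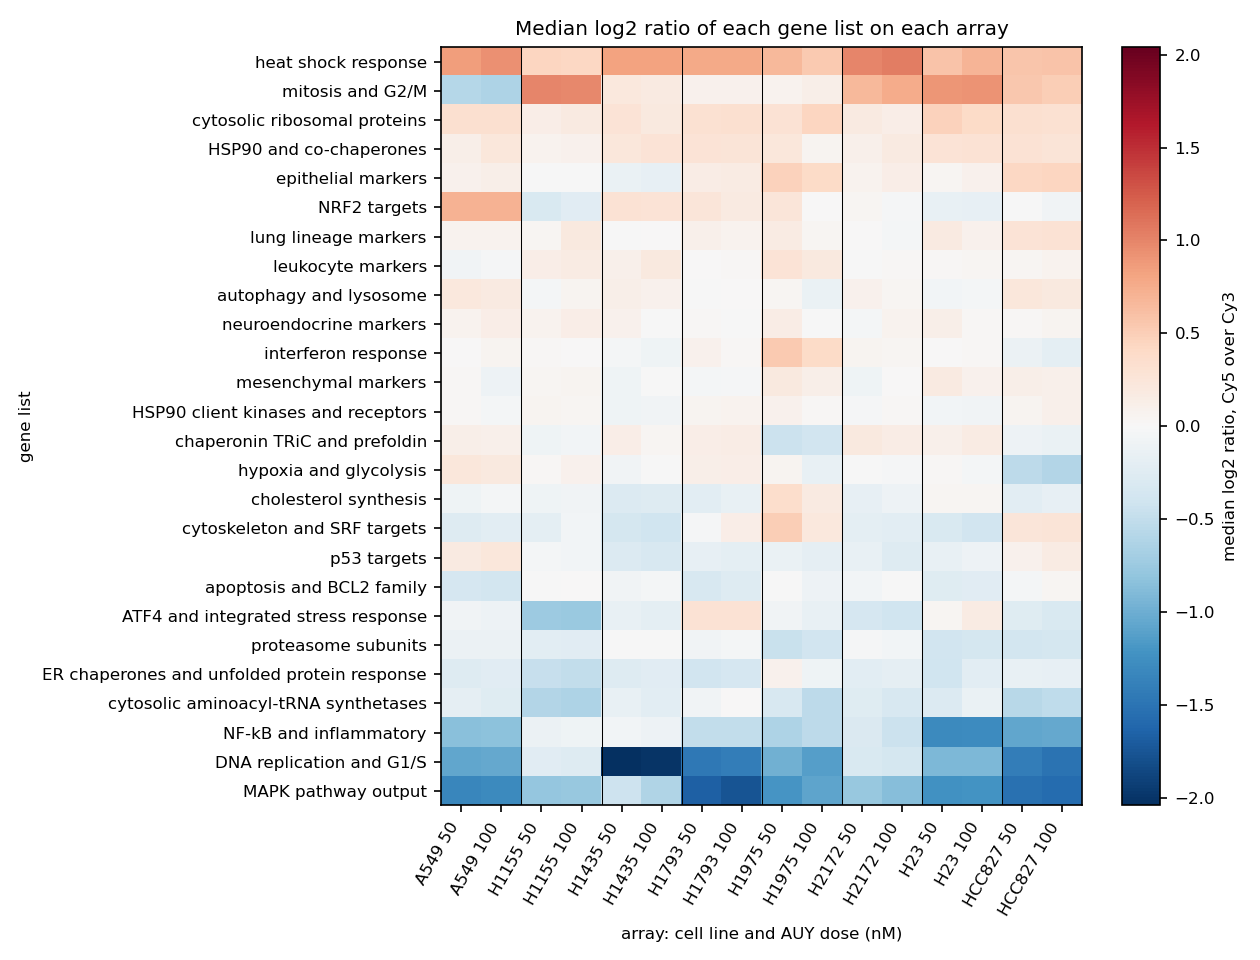
Median log2 ratio (Cy5 over Cy3) of each of the 26 gene lists on each of the 16 arrays, ordered by cell line and dose. The heat shock median lies above 0 on all 16 arrays, and the DNA replication and MAPK output medians lie below 0 in all 8 lines at both doses.

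At 50 nM the same gene groups led. HSPA1A rose by 3.30 ± 1.21 (SD, n = 8 lines) on its brightest probe, which was saturated on 4 of 8 arrays, and by 2.58 and 2.67 on the others. HSP90AA1 rose by 1.95 ± 0.57, HSPA8 by 1.89 ± 0.53, DNAJB1 by 1.03 ± 0.17 and HSP90AB1 by 1.00 ± 0.29. EGR1 fell by 3.75 ± 1.04, DUSP6 by 3.48 ± 1.66, CXCL1 by 2.92 ± 1.59 and CDC45 by 2.30 ± 1.03. HSF1 was at -0.20 ± 0.16 (adjusted p = 0.043) and EGFR at -0.033 ± 0.30 (adjusted p = 0.83), and both turned positive with median centring. In all, 6854 genes passed (limma), 3332 higher and 3522 lower, and 139 rose and 269 fell by 2-fold or more. With median centring 13630 passed, and 69.7% of them were higher. The doses shared 6109 called genes in the same direction and 0 in opposite directions, where independent calls would share 459 higher and 511 lower genes. Both doses used the same lines and dye orientation and possibly the same untreated RNA, so part of the excess may come from these.

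Among the lists at 50 nM, 26 of 34 heat shock genes rose and 44 of 45 DNA replication genes fell, with 28 and 44 when adjusted over the list alone. MAPK output had 18 lower members of 24 (21 when adjusted over the list alone), NF-kB genes 11 of 27 (16) and mitosis genes 14 higher of 40 (16). Camera called 10 lists, the ones called at 100 nM except the ATF4 list (adjusted p = 0.059), which passed in 7 alternatives (adjusted p from 0.012 to 0.048). They were 4 higher and 6 lower, but with median centring 14 passed, 11 higher and 3 lower, with the proteasome among the higher ones and ER chaperones (adjusted p = 0.24) and tRNA synthetases (adjusted p = 0.46) lost. With an estimated correlation 0 passed, the lowest adjusted p being 0.086. The call for HSP90 and co-chaperones (camera adjusted p = 0.038) was lost with the scanner's ratios and with the deposited table (adjusted p = 0.057 each), without H1435 (adjusted p = 0.070), without H2172 (adjusted p = 0.057) and without H1793 and H2172 together (adjusted p = 0.064).

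The comparison of 100 nM with 50 nM within each line asked whether the higher dose gave a different response. HSPA1A differed by 0.12 (95% interval -0.06 to 0.31) between doses, an uncertain value because its probe was saturated in H1975 and H2172 at 50 nM only. HSPA8 differed by -0.04 (-0.13 to 0.04), DNAJB1 by 0.04 (-0.07 to 0.15) and EGR1 by -0.02 (-0.23 to 0.19). HSP90AA1 had an interval of 0.01 to 0.18 around 0.09. Of the 25677 genes, 0 passed the threshold (limma, lowest adjusted p = 0.9997), and 928 had an unadjusted p under 0.05. Across genes, which are not independent replicates, the mean responses at both doses had a Pearson r of 0.987. With line signs flipped at random, the median r was 0.925. The covariance was 0.119, above the 0.0881 that was the highest of 99 such draws.

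**Figure D3:**
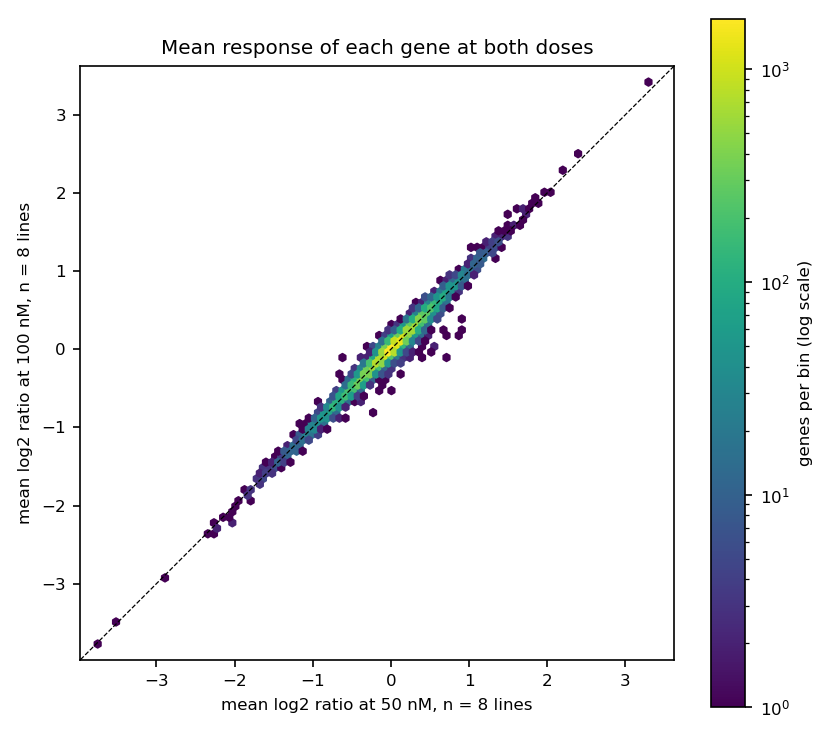
Mean log2 ratio of each gene at 100 nM against its mean at 50 nM (n = 8 lines each). Colour gives the number of genes per bin on a log scale, and the dashed line marks equal responses. Pearson r across genes is 0.987.

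For the dose difference camera called 2 lists, both slightly lower at 100 nM, with 0 members called in either, also when adjusted over the list alone. Hypoxia and glycolysis genes had a mean difference of -0.059 (-0.039 without H1975), with line medians below 0 in 8 of 8 lines (exact sign-flip p = 0.0078, adjusted p = 0.20; camera adjusted p = 0.00024, but adjusted p = 0.86 with an estimated correlation). MAPK output genes had a mean difference of -0.048 (-0.021 without H2172, -0.014 without H1793 and H2172), with line medians below 0 in 6 of 8 lines (exact sign-flip p = 0.047, adjusted p = 0.61; camera adjusted p = 0.0065, but adjusted p = 0.91 with an estimated correlation). The hypoxia call was lost without H1975 (adjusted p = 0.053), whose arrays were on separate slides, in the 5 lines with both arrays on 1 slide (adjusted p = 0.46) and in the 6 lines scanned on 1 day (adjusted p = 0.11). The MAPK call was lost without H1435 (adjusted p = 0.067), without H2172 (adjusted p = 0.34), without H1793 and H2172 (adjusted p = 0.67), with scaling between arrays (adjusted p = 0.13) and with the local backgrounds as in the files (adjusted p = 0.75). Leaving out 1 line also added calls, heat shock genes higher (adjusted p = 0.026) and ribosomal proteins lower (adjusted p = 0.016) without H1975, tRNA synthetases lower without H23 (adjusted p = 0.019) and mitosis genes higher without HCC827 (adjusted p = 0.0085).

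The same data also show how far the response differed between cell lines. CTH was at 4.91 in H23 and at -0.12 in H1435, and at 0.65 in H1435 with median centring. DUSP6 ranged from -6.20 in HCC827 to -0.80 in H2172, where its treated channel was not above the negative controls, so that it was at least 1.60-fold lower there. The stress cytokine GDF15 was at -3.51 in H1155 and 1.97 in H1975. The neuronal pentraxin NPTX1 ranged from -1.89 in HCC827 to 3.47 in H23, and the chemokine CCL2 from -5.17 in H23 to 0.11 in H1975. CCN2 ranged from -3.12 in H23 to 2.03 in HCC827, and CXCL1 from -5.38 in H23 to -0.38 in H1435. The cyclooxygenase PTGS2 ranged from -3.19 in HCC827 to 1.63 in H1435, the adrenergic receptor ADRA1B from -2.63 in HCC827 to 2.05 in H1155, and the endothelin EDN2 from -0.49 in H23 to 4.19 in HCC827. By limma's F-test 21783 genes (84.8%) differed between lines, 8095 of them with a range of line means of 1 or more. These values are means of the 2 arrays of a line, and the test measures only the spread between those arrays. In 5 lines, A549, H1435, H1793, H2172 and HCC827, both arrays were on 1 slide that held no other line of the series. For these lines a difference between lines cannot be told apart from one between slides, which also holds for the gene lists below. Arrays of 1 line correlated with each other across genes at 0.888 to 0.977, and arrays of different lines at 0.322 to 0.612.

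Gene lists differed between lines in 23 of 26 cases (exact permutation test, adjusted). Mitosis genes had a median of -0.61 in A549 and 0.99 in H1155 (exact p = 5e-05, adjusted p = 0.00026). DNA replication genes were at -2.02 in H1435 and -0.25 in H1155 (exact p = 0.00017, adjusted p = 0.00056). MAPK output ranged from -1.72 in H1793 to -0.52 in H1435, NF-kB genes from -1.29 in H23 to -0.08 in H1435, and ATF4 genes from -0.75 in H1155 to 0.30 in H1793 (exact p = 5e-05 each, adjusted p = 0.00026). The heat shock list, above 0 in every line, ranged from 0.43 in H1155 to 1.02 in H2172 (exact p = 0.00042, adjusted p = 0.0010). HSP90 and co-chaperones (exact p = 0.11), lung lineage markers (exact p = 0.076) and neuroendocrine markers (exact p = 0.74) did not pass.

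The genes farthest from the median of the other 7 lines in each line are given as log2 ratios averaged over the 2 arrays of a line, without a test. Single other lines can lie as far out. PTX3 was at -4.00 and NFE2L3 at -2.13 in H23, EDN2 was at 3.83 in A549, and CTH was near 0 in both H1155 and H1435. Some genes had little signal in the other lines, so that ratios near 0 there do not show a lack of response. Either channel was above the negative controls on 4 of the 14 other arrays for VIL1, CXCL12 and PDGFRB and on 5 for CHIA. The number was 6 for LGALS2, SEMA3D, DACT1, CCL20 and AGR3, and 14 for others such as GADD45A and RGS2. In A549 the galectin LGALS2 was at 4.02, SLC51B at 3.97 and the brush border protein VIL1 at 3.61, while PODXL was at -3.21 and EVA1A at -3.00. In H1155 GADD45A was at 2.15 and ID4 at 1.69, with GDF15 at -3.51 and CTH at -0.04 against a median of 3.88 in the other lines, which ran from -0.12 to 4.91. EREG in H1155 was not above the negative controls in either channel. In H1435 CLDN1 was at 0.68, EPPK1 at -1.43 and KLF9 at -1.30, and PTX3 was not above the negative controls. In H1793 SEMA3D was at 2.79, the chemokine CXCL12 at 2.69 and the connexin GJA1 at 2.40, while NPTX2 was at -3.21, CEACAM1 at -3.02 and CTH at 1.00. H1975 had the receptor PDGFRB at 3.81 and ACTA2 at 3.37, with PTX3 at -3.81 and NFE2L3 at -2.41. H2172 had RGS2 at 4.22 and P2RY2 at 1.35, with DACT1 at -2.89, the vitamin D hydroxylase CYP24A1 at -2.84 and FGFR3 at -0.93. H23 had NPTX1 at 3.47, CTH at 4.91 and AREG at 0.19, with CCL2 at -5.17, CCL20 at -4.06 and SCHIP1 at -2.98. HCC827 had the chitinase CHIA at 4.35, EDN2 at 4.19 and AGR3 at 3.85, with DUSP6 at -6.20, FGFBP1 at -3.66 and TBX15 at -2.96.

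HSPA1A signal was lowest in H1155 on all 3 probes, but its ratio only on the brightest. That probe gave a ratio of 0.44 at 100 nM and 0.46 at 50 nM there, with untreated signal not above the negative controls, and between 2.81 and 4.46 at 100 nM in the other 7 lines. On the 3 probes, untreated log2 signal in H1155 was 6.16, 9.95 and 9.55, below the lowest other arrays at 13.17, 11.85 and 11.19. The other 2 probes gave ratios of 2.06 and 1.96 in H1155 at 100 nM, within the 1.93 to 3.05 and 1.71 to 3.40 of the other lines, with H1435 lowest on both. HSPA1A and HSPA1B are nearly identical in sequence, so these probes may read both.

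**Figure D4:**
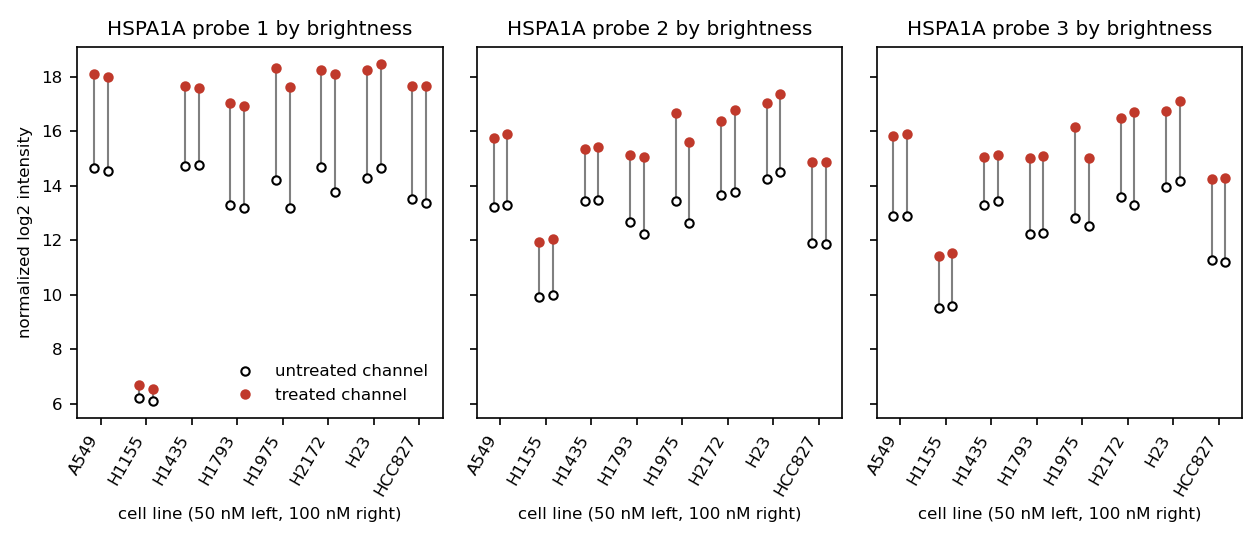
Normalized log2 intensity of the 3 HSPA1A probes in the treated and untreated channels of each line, with 50 nM on the left and 100 nM on the right of each pair. Grey lines join the channels of 1 array, and their length is the log2 ratio. H1155 lies lowest on all 3 probes, with untreated means of 6.16, 9.95 and 9.55.

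The number of genes changed by 2-fold or more at both doses was lowest in H2172, with 138 higher and 195 lower. HCC827 had the most, with 917 higher and 825 lower. In between were A549 with 756 and 770, H1155 with 476 and 447, H1435 with 234 and 621, H1793 with 339 and 517, H1975 with 740 and 618, and H23 with 525 and 703 genes higher and lower. Spike-in slopes, which measure the compression of the scanner's ratios, averaged 0.721 in H2172 and 0.798 in HCC827.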

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

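The 3 tests of HSPA1A in H1155 and the test of signal strength in H2172 were chosen only after the result was seen. Lines whose gap to the nearest other line was large against the whole range (Dixon's 95% critical value) were sought in 304 sets of 8 lines for named genes, 52 for gene lists and 26 for dose differences of lists. They were found in 34, 5 and 8 sets. Chance alone would give about a share of 0.05 only in independent sets that were not selected. Many named genes were chosen because they set a line apart, and genes and lists enter at both doses. The counts are therefore not weighed against that share. The labels give no repeat cultures, and the lines differed in medium. Differences between groups of lines were not tested as an explanation of the 3 patterns weighed here. Only the medium of H2172 is compared below, also after the result was seen.

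HSPA1A in H1155 was at 0.44 at 100 nM and 0.46 at 50 nM on the brightest probe, below the other 7 lines and with signal near background, while its ratios on the other 2 probes, 2.06 and 1.96 at 100 nM, lay within those of the other lines. Failed spots or a failed slide would have touched some probes or 1 array, yet treated signal lay below all other arrays in 6 of the 6 combinations of 3 probes and 2 arrays, which were on separate slides. A sequence mismatch under a single probe as the whole cause is argued against, since untreated signal lay below all other arrays on 3 of 3 probes. H1155 did respond, because the median of its other heat shock genes, 0.40, exceeded 99.98% of random lists matched on intensity. A hypothesis that stays open is that H1155 may express little HSPA1A itself, the remaining signal on 2 probes coming from HSPA1B, and a variant spanning several probes stays open too.

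By limma 0 genes passed between doses, with 928 at an unadjusted p under 0.05, and since no count can fall below 0, the 100 of 100 sign assignments with as many (highest other 0) say nothing about chance. Low precision is argued against for differences of 0.5 on the log2 scale, since 99.67% of genes had a 95% interval within -0.5 to 0.5. A graded response spread thinly over many genes is argued against, since the gain of the response from 50 to 100 nM was 0.021 (95% interval -0.040 to 0.082, exact sign-flip p = 0.51, above 0 in 6 of 8 lines), with an upper end under the 0.1 set in advance, though H2172 alone was at 0.17 and the mean was -0.00034 without it and 0.035 without H1793. Both doses may lie on the plateau of the response, which these 2 doses cannot test further. A smaller gain within that interval stays open, as does untreated RNA shared by the 2 arrays of a line, which would make them more alike.

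H2172 had the fewest genes changed by 2-fold or more at both doses, 333 against 855 to 1742 in the other lines. Compressed ratios, since its spike-in slope was low, are argued against as the whole cause, because division by the slope left 915 in H2172 and at least 1603 in each other line. That slope was given for the scanner's own ratios, so the division is approximate. Weaker signal is argued against, since 73.53% of spots were detected, within 67.54% to 78.27% in the other lines. A smaller response of H2172 stays a hypothesis for the number of genes changed, and differences in culture between lines were not tested. The medium alone is argued against, since H1975, H23 and HCC827 were also grown in RPMI and had 1358, 1228 and 1742 such genes. H2172 was the only line on its slide and on its scan day, so an effect of these cannot be told apart from the line. A smaller response in every gene group is argued against by the heat shock list. Its median was highest in H2172, at 1.02, and lowest in H1155, at 0.43. DNA replication genes went the other way, with a median of -0.33 in H2172, against -2.02 in H1435 and -0.25 in H1155.

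Among the named genes reported here, HSPA1A aside, these single lines lay apart from the other 7. In A549 TNFRSF12A was at -3.15 and AHSA2P at 1.59 at 100 nM, LGALS2 at 4.09 and 3.95 at 100 and 50 nM, PODXL at -3.17 and -3.26, and EVA1A at -3.09 at 100 nM. In H1793 SEMA3D was at 2.67 and 2.91, CXCL12 at 2.57 and 2.82, and GJA1 at 2.45 and 2.36 at 100 and 50 nM. In H1975 PDGFRB was at 3.93 and 3.69. In H2172 DACT1 was at -3.03 and -2.74 and CYP24A1 at -3.44 and -2.25. In H23 TAP1 was at -2.08 and -2.25 and CCL20 at -4.05 and -4.07. In HCC827 FARSB was at -1.54 at 100 nM, PTGS2 at -3.23 and -3.16 at 100 and 50 nM, CHIA at 4.42 and 4.27, and TBX15 at -3.01 and -2.91. Many of these genes were named because they set a line apart, so their number says nothing about chance. In the other lines either channel was above the negative controls on 4 of 14 arrays for CXCL12 and PDGFRB and on 5 for CHIA. The number was 6 for LGALS2, SEMA3D, DACT1 and CCL20, and 14 for PODXL and CYP24A1. Where signal was missing, ratios near 0 do not show a lack of response.

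Among the lists, hypoxia and glycolysis had a median of -0.60 at 100 nM and -0.54 at 50 nM in HCC827, apart from the other lines. The interferon response was at 0.39 and 0.54 in H1975, and TRiC and prefoldin at -0.44 in H1975 at 50 nM. For the difference of 100 minus 50 nM, H1975 lay apart for HSP90 clients at -0.12, cholesterol synthesis at -0.10, apoptosis at -0.11, autophagy at -0.16, ribosomal proteins at 0.17 and SRF targets at -0.35. H1975's arrays were on separate slides and scanned on separate days. So were those of H23, and those of H1155 were on separate slides, yet neither line lay apart for the dose difference of a list. The cause was not tested. MAPK output was apart in H2172 at -0.19 and NF-kB genes in H1793 at 0.085.

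The response differed between cell lines for 21783 genes, 84.8% of all, and for 150 of the 152 named genes, all but PFDN4 and RPL23. Genes named for their range between lines or for a single line had to pass this test to be named. The count of 150 was therefore partly fixed in advance. Other assignments of the 50 nM arrays to lines never called as many, 1 of 100 including the real one, with 6879 the highest other. This argues against a chance pairing of arrays. Chance differences between single cultures are not excluded, since no line has a repeat culture and its untreated RNA may be shared. Differences between slides are not excluded either, since in 5 lines both arrays were on 1 slide that held no other line. For 100 nM and 50 nM against untreated cells 1 of 100 sign assignments called as many genes, the real one with 7265 and 6854. The highest others called 1 and 4, which argues against chance signs of the lines. A gene-specific dye effect shared by all arrays would give the same outcome, so this test cannot tell it from treatment. List medians differed between lines with these ranges. They were 1.77 for DNA replication, 1.59 for mitosis, 1.21 for NF-kB, 1.20 for MAPK output, 1.05 for ATF4, 0.98 for NRF2, 0.79 for hypoxia and 0.75 for SRF targets. They were 0.63 for interferon, 0.60 for heat shock, 0.59 for TRiC, 0.58 for tRNA synthetases, 0.58 for epithelial markers, 0.53 for cholesterol, 0.51 for p53 targets, 0.49 for ER chaperones and 0.42 for the proteasome. They were 0.36 for apoptosis, 0.29 for leukocyte markers, 0.27 for ribosomal proteins, 0.27 for autophagy, 0.20 for mesenchymal markers and 0.16 for HSP90 clients.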

How the results depend on the processing

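The local backgrounds as in the files, an offset of 1, division by the spike-in slope, omission of H1793 and H2172, and both settings by scan day were chosen after seeing the data. Counts of genes stayed within 1.5 times their value under every alternative but median centring, which gave 12478 genes at 100 nM and 13630 at 50 nM. It moved the median of all genes from 0.017 to 0.13 at 100 nM and from 0.018 to 0.16 at 50 nM, and it does not remove the dependence of ratios on intensity, which loess does. The other alternatives gave 5421 to 8818 genes at 100 nM and 4681 to 9027 at 50 nM, 0 between doses, and 14976 to 22321 between lines, where median centring gave 24015. Leaving out each line in turn gave 5819 to 6664 genes at 100 nM, 5456 to 6272 at 50 nM, 0 between doses, 20723 to 22321 between lines, 10 to 12 lists at 100 nM, 9 to 12 at 50 nM, 1 to 3 lists for the dose difference (1 without H1435 and 1 without H2172), and 97 to 102 of the 110 called named genes. The local backgrounds as in the files gave 6071 and 6186 genes at 100 and 50 nM and 17639 between lines.

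With an estimated correlation camera called 0 lists at 100 nM, 0 at 50 nM and 0 for the dose difference, and fry called 10, 11 and 0, with 8 of the 11 called by camera at 100 nM among its 10. For the dose difference 1 list was called after scaling between arrays, 1 with the local backgrounds as in the files, 1 without H1793 and H2172 (MAPK output lost in these 3), 1 in the 5 lines on one slide each and 1 in the 6 lines scanned on one day each (hypoxia lost in both). The cause was not tested, except that the last 3 hold fewer lines.

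Direction, for lists that of camera, reversed only with median centring, and the cause was not tested. The median of all genes went from 0.017 to 0.13 at 100 nM, a smaller change than that of the reversed lists. ER chaperones went from a mean of -0.24 to 0.30 and the proteasome from -0.20 to 0.53. A shift common to all genes is therefore argued against as the whole cause. At 100 and 50 nM, list means became 0.30 and 0.31 for ER chaperones, 0.19 and 0.24 for tRNA synthetases, 0.48 and 0.56 for hypoxia, 0.46 and 0.48 for cholesterol, 0.53 and 0.54 for the proteasome (adjusted p = 0.00018 and 0.00025) and 0.41 and 0.44 for SRF targets. At 100 nM ATF4 became 0.35 and TRiC 0.69, and at 50 nM the TRiC mean went from -0.024 to 0.72 (adjusted p = 0.00028). The hypoxia mean at 50 nM was already above 0, at 0.026, while camera ranked the list as lower. Genes became, at 100 and 50 nM, 0.028 and 0.082 (MARS1), 0.18 and 0.21 (TARS1), 0.054 and 0.13 (PSMC5), 0.021 and 0.0083 (ATG3), 0.081 and 0.090 (PFDN2), 0.62 and 0.59 (CCT2), 0.16 and 0.18 (TUBB3), 0.13 and 0.13 (TPM4), 0.23 and 0.29 (TAGLN2), 0.48 and 0.52 (HSF1), and 0.37 and 0.36 (EGFR). In H1435 PTX3 became -0.36 and CTH 0.65. A reversal is counted where the value in either setting passed the threshold. Of the comparisons for named genes at a dose, 5896 kept direction and side of the threshold, 294 lost the call, 76 gained one and 22 reversed. Signal over background limits dim genes, since 64.7% to 81.0% of spots per array and channel were detected.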

Other observations

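The test of mitosis genes against replication genes was chosen only after the result was seen, while the test of histone genes was set in advance. Replication-dependent histone genes, which are transcribed in S phase, were in no list of the report. Of 61 measured, 12 rose and 7 fell at 100 nM (limma), and their line medians averaged 0.08 ± 0.23 (n = 8 lines, exact sign-flip p = 0.34) at 100 nM and 0.064 ± 0.22 at 50 nM. The members went apart, and these examples were chosen after their values were seen. H4C2 was at -1.12 ± 0.71, H4C13 at -1.10 ± 0.68 and H4C3 at -1.07 ± 0.76, each lower in 8 of 8 lines, while H2AC7 was at 0.71 ± 0.51, H2AC8 at 0.70 ± 0.44 and H1-2 at 0.60 ± 0.50, each higher in 8 of 8 lines. The hypothesis that histone transcripts as a group fell with the DNA replication genes called for a median below 0 in all 8 lines. The measured median lay below 0 in 2 of 8 lines only, A549 at -0.25 and H1793 at -0.23, against a mean of -1.08 for the replication list. This argues against the hypothesis for the histone signal that these arrays read. With median centring these 6 genes kept their directions, with H4C3 at -0.18 and H2AC7 at 1.20, and the histone medians averaged 0.47, below 0 in 0 lines. With scaling between arrays the 6 genes kept their directions too. Most histone transcripts lack a poly(A) tail, and how the labelling reaches them was not tested. The values therefore cannot decide whether the histone transcripts without a tail fell.

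Lines in which replication genes fell less also tended to show higher mitosis genes. Across the 8 lines the medians of both lists had a Pearson r of 0.47 (exact permutation p = 0.24) and a Spearman rho of 0.60 (exact permutation p = 0.13). Without H1435 and H1155, the lines farthest from the median of the replication list, r was 0.33. With 8 lines the relation cannot be told apart from chance. Only this 1 relation was computed across lines. It was chosen after the result was seen, so its unadjusted p-values may be too low.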
